A study of Mus musculus with 6 samples.

How the data were processed

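RNA sequencing libraries from mouse CD4+ T cells were compared between 2 groups, 3 control and 3 idelalisib cultures, all harvested after 72 h under Th1 conditions. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was captured on oligo(dT) beads, fragmented and reverse transcribed with random hexamers. The values are raw read counts per gene as deposited by the authors, 1 column per library, and every column was matched to a library by its name. Per the submitters' processing notes, fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with the mouse genome build mm10. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Where genes overlap on opposite strands their reads could therefore be mixed. Among the genes named, this applies to Kif20a (with Cdc23), Pfkm (with Senp1), Ccna2 (with Exosc9), Shmt1 (with Smcr8), Fdft1 (with Ctsb), Gapdh (with Iffo1), Il2 (with Adad1) and Tgtp2 (with Olfr56). Foxp3 overlaps Flicr on the same strand.

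The deposited table holds 54532 genes with symbols, positions and biotypes, which were used as given. Of its identifiers 99.9% occur in the GENCODE M21 annotation of the same build, and 98.3% of those have identical coordinates there. Total counts per library ranged from 13372318 to 16770452, so a gene at 1 CPM rests on 13.4 to 16.8 reads per library before scaling. The share of counts on mitochondrial genes was 1.92 ± 0.104% in control and 2.02 ± 0.220% in idelalisib libraries (SD, n = 3). No pair of libraries within a group was a duplicate, since the chi-square statistic of their counts per degree of freedom lay between 4.99 and 20.3.

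Genes with too few counts were removed with filterByExpr, at its default minimum count of 10 and minimum total of 15, which left 14530 genes. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersion estimation and a model of group alone. P-values were adjusted with the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Fold changes are idelalisib over control, standard errors were derived from the fold change and its F statistic, and CPM values use the TMM-scaled library sizes. The biological coefficient of variation common to all genes was 0.109.

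A total of 41 gene lists for T cell programmes, signalling, metabolism, proliferation, survival and other cell types were fixed before the data were examined, and 40 had at least 5 tested genes. The granulocyte marker list had 3, Ly6g, Cxcr2 and Mmp9, and was not tested. A symbol with several entries was represented by the entry with the most counts. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with adjustment over the lists. Camera asks whether a list's genes rank higher or lower than the other genes, and was rerun with a correlation estimated per list. Some genes belong to several lists. The genes that could be named were also fixed before the data were examined. They are the 10 called protein-coding genes with the largest rise and the 10 with the largest fall that average at least 1 CPM, have an established symbol and do not overlap in CPM between groups, the 3 called genes with the largest change in each list that average at least 1 CPM (filled up by the smallest p where fewer were called), and 27 genes of T cell biology regardless of outcome. Other genes are identified as chosen after their values were seen. Some genes that met these rules are not reported here.

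The scripts were tested on simulated data with the means, dispersions and library sizes of these libraries. Over 10 simulations of this comparison with 200 changed genes among 14530, 52.1% of genes changed 1.5-fold, 75.7% of those changed 2-fold and 96.8% of those changed 4-fold were called in the right direction. Unchanged genes made up 8.2% of calls on average (5.6% to 10.9%), above the nominal 5% in every simulation. The test first ran on 1 simulation with a limit of 10% for this share, which its 10.9% exceeded. The other simulations were added after that and the limit was raised to 15% for the mean, with the method itself unchanged, so calls near the threshold are less certain than their adjusted p states. A list shifted by 0.5 on the log2 scale was called and no other list was. Simulated genes were drawn independently of each other, so this did not test lists whose genes vary together. The 200 changed genes are also far fewer than the 6479 called in the data, so the shares above need not carry over.

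Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library size alone), DESeq2 1.42.0, limma-voom, other count filters (the lowest of which asked for no more than 1 count), a minimum log2 fold change of 1, an adjusted p under 0.01, protein-coding genes alone, a model with the replicate number as a block, each library left out in turn and, for lists, an estimated correlation and the fry test. GC content, transcript length and the share of 50-base words found in other genes were computed from the longest GENCODE M21 transcript of each gene.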

Results

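CD4+ T cells purified from the spleens of C57BL/6 mice were kept for 72 h under conditions that polarise towards T helper 1 (Th1) cells, with or without idelalisib, an inhibitor of the delta isoform of phosphoinositide 3-kinase (PI3K). Poly(A) RNA from 3 biological replicates of each group was sequenced, and read counts were deposited for 54532 genes in 6 libraries. The series asks what idelalisib does to the activation, proliferation, differentiation and survival of these cells. Its dose, and whether control cultures received the solvent, are not given in the sources used here. Total counts were 16770452, 16014484 and 14879325 in the control libraries and 14335571, 13372318 and 16035945 in the idelalisib libraries. The labels do not say whether replicates came from separate mice, so the p-values below measure the spread between these cultures, which may be technical.

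Idelalisib changed a large part of the transcriptome. Of 14530 genes tested, 3223 were higher and 3256 were lower with idelalisib at an adjusted p under 0.05 (edgeR quasi-likelihood test, n = 3 per group), which is 44.6% of the genes tested. Among these, 838 higher and 866 lower genes differed by at least 1 on the log2 scale. The first principal component held 67.9% of the variance and separated the groups, and the correlation of log2 CPM (counts scaled to a common library total) was 0.983 to 0.990 within groups against 0.95 to 0.962 between them. Idelalisib replicate 2 stood apart from the other idelalisib libraries on the second component, which held 11.8%, and without it 3599 genes were higher and 3581 lower. Scaling by library size alone called 4832 genes higher and 2219 lower, 68.5% of calls on the higher side against 49.7%, and moved the median log2 fold change of all genes from 0.01 to 0.16. Folds below are on the scale of trimmed mean of M-values (TMM) factors.

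Genes induced by interferons rose with idelalisib. All 31 tested members of the type I interferon response list were higher, with a median log2 fold change of 2.11 (camera adjusted p = 1.67e-50), and all 31 were higher when adjusted over the list alone. Mx1, an interferon-induced GTPase gene (ENSMUSG00000000386, mm10 chromosome 16, 97447035 to 97462907), rose from 0.182 ± 0.113 to 12.5 ± 2.51 CPM (SD, n = 3), a log2 fold change of 6.07 (SE 0.34, edgeR adjusted p = 2.16e-08). Xaf1, a pro-apoptotic interferon target on chromosome 11, rose from 1.04 ± 0.592 to 22.7 ± 0.461 CPM, or 21.6-fold. Ifi44 had 2 counts over the control libraries and 294 over the idelalisib libraries, a ratio of 144 with an exact 95% counting interval of 39.5 to 1190. The genes with large rises also included members of interferon-induced families: the oligoadenylate synthetase-like gene Oasl2, the nucleotide kinase Cmpk2 and the RNA helicase Ddx60, with log2 fold changes of 4.26, 4.21 and 4.03. The DNA sensor family member Ifi206 had 4, 0 and 0 counts in the control libraries and 40, 37 and 48 in the idelalisib libraries, so its fitted log2 fold change of 4.82 rests on control replicate 1 and was 8.35 without it. All these genes were near 1 CPM or lower in control cells, so their folds rest on few control counts.

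The interferon gamma response list also rose, with 25 of 31 tested genes higher and 1 lower (median log2 fold change 0.72, camera adjusted p = 1.13e-17; 27 higher and 1 lower when adjusted over the list alone). With a correlation estimated from the data its adjusted p = 0.0521. Iigp1, an immunity-related GTPase, rose 9.79-fold from 6.91 ± 1.52 to 67.7 ± 14.7 CPM (log2 fold change 3.29, SE 0.18, edgeR adjusted p = 1.04e-07). The serpin Serpina3g and the T cell-specific GTPase Tgtp2 had log2 fold changes of 2.61 and 2.05. The exception, chosen after its values were seen, was Irf8, an interferon-responsive transcription factor, at -0.53 (SE 0.08, edgeR adjusted p = 0.000112). Beside these gene groups, 7 of 14 B cell markers were also higher with idelalisib, each at low counts (Bank1 from 0.749 ± 0.175 to 2.09 ± 0.461 CPM).

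**Figure D1:**
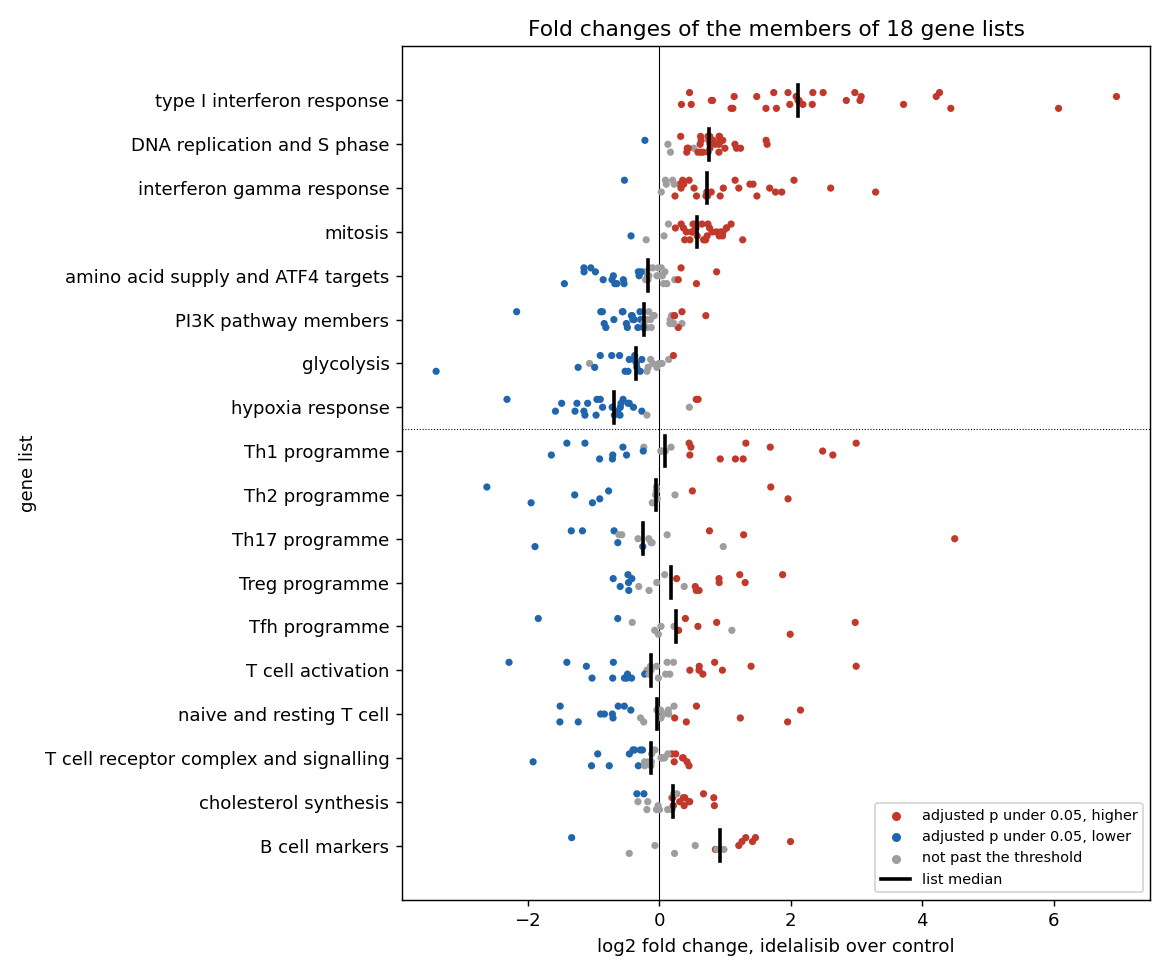
Fold changes of the tested members of 18 gene lists. The x axis is the log2 fold change of idelalisib over control, each point is a gene coloured by its edgeR call, black bars are list medians, and the 8 lists above the dotted line passed the list test. The median of the type I interferon list lies at 2.11 and that of the hypoxia list at -0.68.

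Ifng itself, the signature cytokine of Th1 cells (ENSMUSG00000055170, mm10 chromosome 10, 118441046 to 118445892), fell 2.65-fold, from 387.9 ± 29.0 to 146.3 ± 14.8 CPM (log2 fold change -1.41, SE 0.09, edgeR adjusted p = 9.25e-08). Tbx21, which encodes the Th1 master regulator T-bet, was at 113.4 ± 5.56 and 115.2 ± 6.19 CPM, a log2 fold change of 0.02 (SE 0.08) that did not pass the test (edgeR adjusted p = 0.837). The Th1 list as a whole held 11 higher and 9 lower genes of 25 and was not called (camera adjusted p = 0.185). Its largest rises were in Il2, the T cell growth factor, from 3.02 ± 0.423 to 24.3 ± 15.3 CPM (log2 fold change 3.00, SE 0.54, edgeR adjusted p = 0.00778; 2.37 without idelalisib replicate 2), in the chemokine gene Ccl5 at 2.64 and in Ly6c2 at 2.48. Other cytokines moved apart. Tnf and Il10 rose by 0.46 and 0.55 on the log2 scale, Il4 rose from 1.38 ± 0.306 to 4.46 ± 1.07 CPM, and Il24 fell by 1.95 on the log2 scale. Of 24 effector cytokine genes, 11 were higher and 4 lower (camera adjusted p = 0.254).

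Lists for the other helper T cell programmes were not called either. The Th2 list held 3 higher and 6 lower of 15 genes (camera adjusted p = 0.424), the Th17 list 3 higher and 6 lower of 17 (0.741), the regulatory T cell list 9 higher and 6 lower of 20 (0.294) and the follicular helper list 6 higher and 2 lower of 14 (0.139). Within them, Slamf6, a homophilic surface receptor of T cells, rose from 11.7 ± 0.759 to 92.0 ± 25.9 CPM (log2 fold change 2.98, SE 0.19, edgeR adjusted p = 1.53e-06) and Pou2af1, a transcriptional coactivator, rose by 1.99 on the log2 scale, while Bcl6, the follicular helper regulator, fell by 1.84. Ahr, the aryl hydrocarbon receptor, fell by 1.34 on the log2 scale. The regulatory T cell genes Gpr83 and Lrrc32 had log2 fold changes of 1.88 and 1.31. Foxp3, the regulatory T cell master regulator, was at 5.23 ± 0.382 and 7.72 ± 1.28 CPM (log2 fold change 0.56, SE 0.19, edgeR adjusted p = 0.0261), and lost its call without control replicate 1, 2 or 3 or idelalisib replicate 2, with adjusted p up to 0.0996.

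Activation and homing genes were split. Higher genes included Il2ra, the high-affinity interleukin-2 receptor chain, from 1530 ± 67.7 to 2326 ± 109 CPM (log2 fold change 0.60, SE 0.08, edgeR adjusted p = 2.84e-05), and Cd69, an early activation marker, at 0.84. Klf2, which encodes a regulator of T cell trafficking, rose 4.43-fold. Lower genes included Nr4a2, a nuclear receptor induced by T cell receptor signals, at -2.29, the memory marker Cd44 at -0.49, the interleukin-7 receptor chain Il7r at -0.62 and the Tec kinase Txk at -1.51. The chemokine receptor gene Ccr7 had a log2 fold change of -0.24 (SE 0.09) that did not pass the test (edgeR adjusted p = 0.0535). It passed in 7 alternatives, among them DESeq2 (adjusted p = 0.0368), limma-voom (0.0418) and the fit without idelalisib replicate 3 (0.000746), and its adjusted p reached 0.473 scaled by library size alone. The T cell activation list held 8 higher and 11 lower of 30 genes (camera adjusted p = 0.537), the naive and resting T cell list 6 higher and 10 lower of 25 (0.537) and the list of FOXO-induced transcripts 6 higher and 8 lower of 22 (0.537). In the cytotoxic effector list 3 of 16 genes were higher and 6 lower (0.186). Fasl, the death receptor ligand, fell from 20.3 ± 0.818 to 4.43 ± 0.951 CPM and Gzmc fell by 1.95 on the log2 scale, while granzyme B, Gzmb, was at 415.2 ± 37.5 and 376.0 ± 28.9 CPM (edgeR adjusted p = 0.205).

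Genes of the cell cycle rose. In the DNA replication and S phase list 32 of 36 genes were higher and 1 was lower (median log2 fold change 0.75, camera adjusted p = 2.94e-22; 33 higher and 1 lower when adjusted over the list alone). The ribonucleotide reductase subunit Rrm2 rose 3.08-fold, from 48.9 ± 2.20 to 151.0 ± 4.23 CPM (log2 fold change 1.62, SE 0.08, edgeR adjusted p = 9.07e-09). The transcription factor E2f8 and the replication licensing factor Cdc6 rose by 1.64 and 1.24 on the log2 scale. In the mitosis list 29 of 33 genes were higher and 1 was lower (median 0.58, camera adjusted p = 1.35e-14; 29 higher and 2 lower when adjusted over the list alone). With an estimated correlation its adjusted p = 0.098. Kif20a, a mitotic kinesin, Cenpf, a kinetochore protein, and cyclin A2, Ccna2, had log2 fold changes of 1.27, 1.09 and 1.02. Mki67, the proliferation marker Ki-67, rose from 652.7 ± 12.8 to 973.4 ± 175 CPM. The exceptions, chosen after their values were seen, were the centromere histone Cenpa at -0.43 (edgeR adjusted p = 0.000705) and E2f2 at -0.22. The call of E2f2 (edgeR adjusted p = 0.0482) was lost without control replicate 1 or 3 or idelalisib replicate 1 or 2, with adjusted p up to 0.183. Myc was at 222.1 ± 17.0 and 258.0 ± 18.4 CPM (edgeR adjusted p = 0.0530). It was called with upper-quartile scaling (adjusted p = 0.0276), library size alone (0.00287), the lowest count filter (0.0497) and without idelalisib replicate 1 or 3 (0.0358 and 0.0486), while its adjusted p reached 0.251 without control replicate 2.

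Genes of hypoxia and of glucose metabolism fell. In the hypoxia response list 23 of 27 genes were lower and 2 were higher (median log2 fold change -0.68, camera adjusted p = 1.02e-11; 24 lower and 2 higher when adjusted over the list alone), but with an estimated correlation its adjusted p = 0.605. Ndrg1, a stress-induced growth regulator, fell from 481.6 ± 30.1 to 171.9 ± 54.0 CPM, the collagen prolyl hydroxylase P4ha2 fell from 111.8 ± 9.49 to 37.3 ± 7.87 CPM and the peptide hormone gene Adm fell by 2.32 on the log2 scale. The exceptions, chosen after their values were seen, were the oxygen sensor gene Egln3 at 0.59 (edgeR adjusted p = 8.32e-05) and Stc2 at 0.56 (0.0262). The call of Stc2 held only without idelalisib replicate 2 among the 6 fits that left out 1 library, and its adjusted p reached 0.114. In the glycolysis list 15 of 25 genes were lower and 1 was higher (median -0.35, camera adjusted p = 0.000262; 16 lower and 1 higher when adjusted over the list alone), and with an estimated correlation its adjusted p = 0.605. Scaled by library size alone its median was -0.20 (adjusted p = 0.00132). The glucose transporter Slc2a3 fell from 1019 ± 33.6 to 432.7 ± 50.7 CPM (log2 fold change -1.24, SE 0.09, edgeR adjusted p = 2.27e-07), and the phosphofructokinase Pfkm fell by 0.98 on the log2 scale. The monocarboxylate transporter Slc16a1, chosen after its values were seen, was higher by 0.22 (edgeR adjusted p = 0.0460) and kept that call only without idelalisib replicate 3 among those 6 fits, with adjusted p up to 0.150. Gapdh was at 122, 493 and 380 CPM in the control libraries and 29.9, 27.9 and 36.7 CPM in the idelalisib libraries (log2 fold change -3.39, SE 0.63, edgeR adjusted p = 0.0151). Its adjusted p rose to at most 0.0598 without control replicate 3 or any 1 of the 3 idelalisib libraries, and 27.8% of its transcript's 50-base words occur in other genes.

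Genes of amino acid supply and of the PI3K pathway were lower by a smaller margin. In the amino acid supply and ATF4 target list 15 of 35 genes were lower and 4 were higher (median log2 fold change -0.18, camera adjusted p = 0.0157; the same counts, 15 and 4, when adjusted over the list alone), and with an estimated correlation its adjusted p = 0.605. Ddit4, which encodes the mTORC1 inhibitor REDD1, fell from 449.2 ± 12.1 to 202.7 ± 42.2 CPM, and the stress regulator Nupr1 fell by 1.44 on the log2 scale. The 4 higher genes, chosen after their values were seen, were Shmt1, Wars, Sesn2 and Slc1a4, at 0.87, 0.57, 0.33 and 0.29. The call of Sesn2 was lost without control replicate 2 or 3 or idelalisib replicate 1, and that of Slc1a4 without any control library or idelalisib replicate 1, with adjusted p up to 0.0625 and 0.167. Of 37 PI3K pathway members 18 were lower and 5 higher (median -0.24, camera adjusted p = 0.0416; 18 lower and 7 higher when adjusted over the list alone), and with an estimated correlation the adjusted p = 0.605. Scaled by library size alone, neither list passed (medians -0.02 and -0.08, adjusted p = 0.0518 and 0.147), and the PI3K list also missed without idelalisib replicate 3 (adjusted p = 0.0528). The regulatory subunit gene Pik3r6 fell by 2.17 on the log2 scale, the gamma catalytic subunit gene Pik3cg by 0.89 and the mTORC2 subunit gene Rictor by 0.86. The higher members included, chosen after their values were seen, the phosphatase gene Phlpp2 at 0.71, Akt1 at 0.34, Pik3r5 at 0.29 and Akt2 at 0.23. The call was lost for Pik3r5 without control replicate 2 or 3 and for Akt2 without any control library or idelalisib replicate 1 or 3, with adjusted p up to 0.0789 and 0.135.

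The drug's target gene was not among the called genes. Pik3cd, which encodes the catalytic subunit p110 delta (ENSMUSG00000039936, mm10 chromosome 4, 149649168 to 149702571), was at 783.0 ± 6.32 CPM in control and 687.0 ± 69.0 CPM in idelalisib libraries (log2 fold change -0.19, SE 0.08, edgeR adjusted p = 0.0820). Of the 17 alternatives it passed in 2, without idelalisib replicate 3 (adjusted p = 0.0184) and among protein-coding genes alone (0.0432), and its adjusted p reached 0.759 scaled by library size alone. The regulatory subunit gene Pik3r1 and the PI3K inhibitor gene Pik3ip1 had log2 fold changes of -0.14 and -0.09 (edgeR adjusted p = 0.233 and 0.575). Genes of the T cell receptor complex and its signalling included 10 lower and 7 higher of 30 (camera adjusted p = 0.0854). Cblb, a ubiquitin ligase that restrains T cell activation, fell from 850.5 ± 14.9 to 224.8 ± 20.8 CPM (log2 fold change -1.92, SE 0.09, edgeR adjusted p = 3.94e-09). Zap70, the kinase that relays the T cell receptor signal, fell from 641.4 ± 51.7 to 313.9 ± 34.4 CPM, and the phosphatase gene Ptpn22 fell by 0.94 on the log2 scale.

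**Figure D2:**
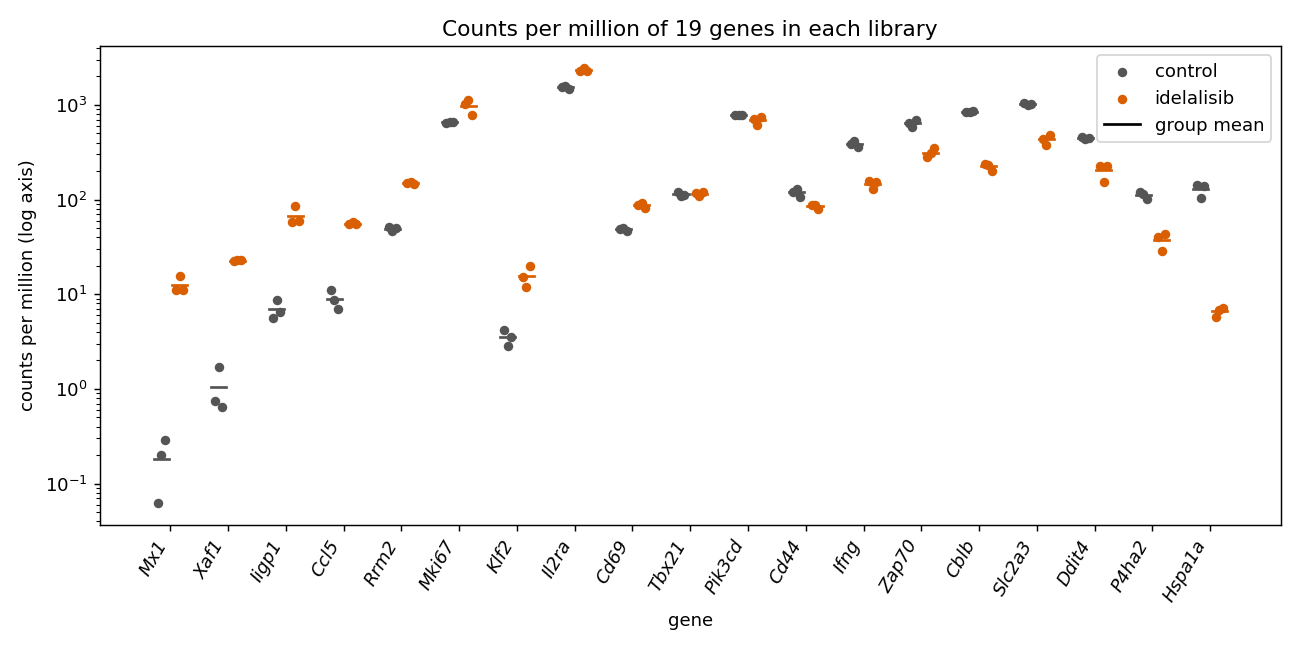
Expression of 19 genes, in CPM, in each of the 6 libraries. The y axis is logarithmic, each point is a library, grey is control, orange is idelalisib, and horizontal bars are group means (n = 3). Ifng lies at 387.9 CPM in control and 146.3 CPM with idelalisib, while Tbx21 lies at 113.4 and 115.2 CPM.

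Among the genes with the largest falls were inducible heat shock genes. Hspa1a fell from 128.3 ± 21.3 to 6.61 ± 0.783 CPM (log2 fold change -4.28, SE 0.14, edgeR adjusted p = 8.90e-10) and Hspa1b from 210.0 ± 40.4 to 13.1 ± 6.13 CPM. These neighbours on chromosome 17 share 66.3% and 62.3% of their transcripts' 50-base words with other genes, so the division of reads between them is uncertain. The small heat shock gene Hspb1 had a log2 fold change of -3.38. The immediate early and heat shock list held both directions, with 6 higher and 9 lower of 22 genes (camera adjusted p = 0.186). Other large falls were in Maats1 at -4.68 (-5.57 without idelalisib replicate 2), in Chl1, a cell adhesion gene, from 18.4 ± 2.42 to 1.27 ± 0.264 CPM, and in the ubiquitin ligase gene Trim69 at -3.29.

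Some genes listed as markers of cells other than CD4+ T cells rose with idelalisib. Their rise does not show whether such cells were more frequent. Of 14 B cell markers 7 were higher and 1 was lower (camera adjusted p = 0.208). Bank1 and Cd79b rose to 2.09 ± 0.461 and 1.84 ± 0.436 CPM, while the immunoglobulin kappa constant gene Igkc fell from 8.71 ± 1.38 to 3.46 ± 0.532 CPM. Of 7 tested stromal and endothelial markers 4 were higher (camera adjusted p = 0.164), among them Kdr, which rose from 0.201 ± 0.174 to 3.24 ± 1.19 CPM (log2 fold change 3.96, or 4.89 without control replicate 2), and Lum, which reached 6.59 ± 1.74 CPM. In the list of CD8 T cell and natural killer cell markers 4 of 10 were higher (0.294), including Eomes from 2.88 ± 0.316 to 9.30 ± 1.88 CPM, and 3 of 8 gamma delta T cell markers were higher (0.254). Eomes is also a member of the Th1 list, so its rise does not by itself point to other cells. Of 9 monocyte, macrophage and dendritic cell markers 2 were higher, Cd74 and H2-Aa, and 2 were lower, Cd68 and H2-Eb1, the last chosen after its values were seen. The median of this list was -0.54 while its mean was 0.05 (camera adjusted p = 0.824). Only 3 of 18 granulocyte markers could be tested. Ly6g rose from 38.8 ± 2.77 to 116.7 ± 11.2 CPM and Cxcr2 from 10.3 ± 1.91 to 18.4 ± 3.83 CPM, while Mmp9 was under 1 CPM in both groups (edgeR adjusted p = 0.646). The Cd4 transcript was at 554.0 ± 38.1 and 473.9 ± 53.1 CPM (edgeR adjusted p = 0.0614). It was called with DESeq2 (adjusted p = 0.0446), the lowest count filter (0.0492), protein-coding genes alone (0.0353) and without idelalisib replicate 3 (0.0434), while its adjusted p reached 0.551 scaled by library size alone.

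Lists tied to survival and to other metabolism were not called. Of 22 pro-apoptotic genes 8 were higher and 5 lower (camera adjusted p = 0.855), and of 15 anti-apoptotic genes 1 was higher and 4 were lower (0.375). Cholesterol synthesis genes included 11 higher and 2 lower of 25 (0.151), oxidative phosphorylation genes 2 higher and 6 lower of 37 (0.498), and ribosome biogenesis genes 10 higher and 6 lower of 34 (0.484). The lists of the unfolded protein response, p53 targets, fatty acid synthesis, fatty acid oxidation and lysosome, cell cycle inhibitors, chemokine and homing receptors, inhibitory receptors, STAT5 and IL-2 targets, other MYC targets and erythroid and platelet markers had camera adjusted p from 0.254 to 0.797. In all, 4 of 40 tested lists were called higher and 4 lower. With an estimated correlation 2 calls held, the type I interferon response (adjusted p = 0.00343) and DNA replication and S phase (adjusted p = 0.00623), and no list was called lower.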

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

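All alternatives here were chosen before the data were examined. The counts of called genes stayed within 1.5 times of 3223 higher and 3256 lower under RLE, upper-quartile and library-size scaling, DESeq2, limma-voom, both other filters and protein-coding genes alone, and no gene was called in opposite directions. Requiring an absolute log2 fold change of 1 left 838 and 866 genes, and an adjusted p under 0.01 left 2138 higher genes, both by construction. Leaving out 1 library gave 2472 to 3599 higher and 2617 to 3581 lower genes. With the replicate number as a block, 2910 genes were higher and 3051 lower, and 4 lists were called each way. Deviations of same-numbered libraries from their group means correlated at 0.08, -0.13 and -0.10. These values show no strong effect shared by same-numbered libraries. With so few libraries they cannot tell whether the cultures were paired.

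The 4 lists called higher and 4 called lower became 2 and 0 with an estimated correlation. With fry, which does not compare a list with other genes, they became 13 and 14. The estimate was larger than the preset for 6 of these 8 lists, but the other 2 weakened as well. The type I interferon list went from a camera adjusted p of 1.67e-50 to 0.00343 at an estimate of 0.005. The DNA replication and S phase list went from 2.94e-22 to 0.00623 at -0.006. The size of the correlation alone therefore does not account for the weakening, and its cause was not tested. Library size alone left 2 lists lower. Leaving out 1 library gave 4 to 6 lists higher and 4 to 5 lower.

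Of 101 genes named, 92 were called, and none of these changed direction in any of the 17 alternatives. In all, 59 kept their call throughout, and 11 lost it in at least 1 alternative other than the minimum fold or the stricter threshold. Apart from fits without 1 library, these losses were Slc16a1 and Slc1a4 (DESeq2, the lowest count filter, the replicate block and protein-coding genes alone, and for Slc16a1 also RLE), E2f2 and Fdft1 (upper quartile, library size alone, the lowest count filter and the replicate block), Akt2 (the block and protein-coding genes alone), Gapdh (the block) and Mvd (library size alone). Their adjusted p reached 0.0802, 0.0728, 0.551, 0.443, 0.0666, 0.0579 and 0.184 there. Of the 9 genes not called, 4 gained a call in at least 1 alternative (Ccr7 in 7, Myc in 5, Cd4 in 4 and Pik3cd in 2), and 5 changed sign near 0. Pik3r1, Pik3ip1 and Gzmb had log2 fold changes of 0.02, 0.068 and 0.012 scaled by library size alone. Leaving out 1 library gave -0.138 to 0.038 for Pik3ip1 (positive without idelalisib replicate 2) and -0.007 to 0.072 for Tbx21 (negative without control replicate 2) and -0.047 to 0.549 for Mmp9 (negative without control replicate 2 or idelalisib replicate 3), and Tbx21 was at -0.003 among protein-coding genes alone. The cause was not tested. Depth limits the genes near or under 1 CPM in control cells, such as Ifi44 and Kdr.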

Other observations

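The explanations weighed in this part, the bounds they were held to and the gene sets of its first 2 paragraphs were chosen after the results were seen. The gene calls, the fits without 1 library and the lists cited from the report were not. Beyond the lists fixed in advance, cytosolic ribosomal protein genes moved together. Of 84 such genes 73 were lower and 2 higher with idelalisib, with a median log2 fold change of -0.44 that stayed between -0.44 and -0.28 under the 4 scalings (camera adjusted p = 1.46e-13 over 8 sets; adjusted p = 0.162 with an estimated correlation). Their share of all counts was 7.82 ± 0.140% in control and 6.29 ± 0.348% in idelalisib libraries (SD, n = 3). Small nucleolar RNA host genes, many of which share a promoter type with ribosomal protein genes, were lower in 8 of 11 cases (median -0.66, camera adjusted p = 0.000148; adjusted p = 0.0679 with an estimated correlation). Other genes of translation were not called as sets: mitochondrial ribosomal protein genes held 11 higher and 10 lower of 79 (camera adjusted p = 0.845) and genes with elongation factor symbols 2 higher and 5 lower of 12 (0.174). The latter set was picked by the start of the symbol alone. It can therefore include genes that are not elongation factors, and does not show how the factors themselves behaved. Of 13 T cell receptor beta joining segments 10 were lower (median -0.94, camera adjusted p = 0.00113; adjusted p = 0.289 with an estimated correlation).

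Other families moved as well. All 11 guanylate-binding protein genes (median log2 fold change 1.68, camera adjusted p = 1.50e-29; adjusted p = 0.00719 with an estimated correlation) and all 8 schlafen genes (median 1.28, camera adjusted p = 2.17e-12; adjusted p = 0.0643 with an estimated correlation) were higher. Both are interferon-inducible families. Several of the guanylate-binding protein genes and some of the schlafen genes are already members of the interferon lists. These sets therefore partly count the same genes again and are not separate evidence. Of 408 C2H2 zinc finger genes 134 were higher and 49 lower (median 0.26, or 0.42 scaled by library size alone, camera adjusted p = 0.00188; adjusted p = 0.283 with an estimated correlation). The long noncoding RNA Ifngas1, which lies beside Ifng on chromosome 10 (118502035 to 118556525), rose from 0.659 ± 0.189 to 5.56 ± 1.30 CPM (log2 fold change 3.05, SE 0.31, edgeR adjusted p = 4.46e-06) while Ifng fell. Txnip and its relative Arrdc4, both targets of the glucose-sensing transcription factor MondoA, rose by 1.54 and 1.56 on the log2 scale.

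The rise of interferon-stimulated genes beside a fall of Ifng is a pattern to follow up. The choice among the 4 scalings is argued against as its source. They placed the median of all genes between 0.004 and 0.164, and that of the type I interferon list at 2.10 or higher. All 4 are relative, so a change in RNA per cell was not addressed. A trend with GC content or transcript length is argued against as well. It was small (SD 0.088 on the log2 scale), and the list median was 2.10 after its removal. RNA from B cells or antigen-presenting cells is argued against too, because the summed CPM of both marker lists rose by 8.46 while that of the interferon list rose by 1169. The marker sum is net of genes that moved both ways. Cd74 rose from 31.26 to 56.92 CPM, for example, while Cd68 fell from 16.65 to 10.49 CPM. Interferon made in the treated cultures stays open: the type I interferon genes together had 2, 5 and 3 counts in control and 5, 8 and 13 in idelalisib libraries (exact 2-sided permutation p = 0.20, where 0.10 is the smallest possible).

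Replication genes rose while hypoxia genes fell, though with an estimated correlation the hypoxia list was not called (adjusted p = 0.605) and the replication list was (adjusted p = 0.00623). The choice among the 4 scalings does not account for the opposite shifts, as the hypoxia median was -0.53 or lower and the replication median 0.75 or higher under each. Removing the trend with GC content and length left them at -0.71 and 0.72. A general fall of mTORC1-dependent transcription would also lower cholesterol synthesis genes, of which 11 were higher and 2, Fdft1 and Mvd, lower. This argues against it as the whole cause, though weakly, since the list as a whole was not called (camera adjusted p = 0.151). It was also the only list weighed here. The glycolysis list and the amino acid supply and ATF4 list were called lower at the preset correlation (camera adjusted p = 0.000262 and 0.0157). A partial role therefore stays open. The calls of Fdft1 and Mvd were lost without any control library or idelalisib replicate 1, and that of Mvd also without idelalisib replicate 2, with adjusted p up to 0.175 and 0.139. Control cultures that were denser or poorer in nutrients could also give lower amino acid supply and ATF4 targets with idelalisib, and their median was -0.18, but -0.02 scaled by library size alone. This cannot be told apart from a direct effect of the drug, since cell numbers were not used here.

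The fall of Gapdh exceeded that of every other glycolysis gene, the lowest of which was Slc2a3 at -1.24, so it is not explained by a fall that the list shares. Reads shared with near-identical copies may bear on it: 303 other genes above 50 CPM share at least as much sequence, and their median log2 fold change was -0.24. The 5 annotated pseudogenes held 0 to 5 counts per library, so the missing reads were not counted there. Copies outside the annotation were not examined. Gapdh was also low in both groups, at 331.9 CPM in control and 31.5 CPM in idelalisib libraries. The glycolysis genes Pgk1 (2743 and 2093 CPM) and Tpi1 (1194 and 975.5 CPM) were far above it, while others such as Pfkm (126.1 CPM in control) were below its control level. Genes with more shared sequence than Gapdh fell by different amounts. Pgk1 shares 68% of its 50-base words and had a log2 fold change of -0.39, while Hspa1a shares 66.3% and had -4.28. Reads dropped as ambiguous are in no column of the table, which leaves this explanation and a real change open.

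Splits of the 6 libraries into other groups of 3 number 10 with the real one included, too few for a share under 0.05. The real split called 6479 genes and the highest of the other splits 0, which makes it 1 of 10 with as many. For lists, 5 of the 10 splits called at least as many as the 8 of the real split, and the highest of the others called 12. Every other split puts libraries of both groups on each side. Part of the treatment difference therefore remains between its sides, and it also adds to the spread within them. Neither the gene counts nor the list counts of these splits show what would arise without a treatment difference.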
